A study of Mus musculus with 4 samples.

How the data were processed

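RNA from the prefrontal cortex of female mice was measured on 4 single-channel expression arrays, 2 for control pools of the FVB/N strain and 2 for pools of transgenic mice that overexpress human synaptic AChE, each pool made from 4 mice per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 2 pools of a group came from different mice, so p-values measure only the spread between these samples, which may be technical. No date, lot or scan is given by the labels used here, so a batch that follows the groups cannot be told apart from the group. The strain background of the transgenic mice is not stated in the labels, so a difference of strain is not excluded for any gene.

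The deposited table holds 1 intensity per probe set and array on a linear scale. The unit is not named by a header or label and was read from the values, which are never negative and have 1 decimal. The authors' tool for deriving an intensity from the probes, and the annotation build, are not given in the sources used here. In each column the mean of the values between the 2nd and 98th percentiles was 250.1, 250.1, 250.2 and 250.3, so each array had been scaled to a common level before deposit. Medians differed by at most 1.85% and upper quartiles by 2.29%, within the 10% fixed as the limit for using the values as deposited, so no further normalization was applied.

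Of 12488 probe sets, 66 control probe sets were left out. Gene names came from the platform annotation, which is old, and 10817 symbols were updated through gene identifiers to the RefSeq gene table of mouse assembly GRCm38.p6, while 16 kept the platform's symbol. A single gene was named for 10833 probe sets, several for 396 and none for 1193, and genes were named only from the first kind, which covered 8251 genes. No positions are given, since no build is named for the probes. Values were floored at the 25th percentile of all values (19.675) and log2-transformed. Between 24.0% and 25.9% of the values of an array lay at the floor. A fold is 2 to the power of the log2 change, a ratio of geometric means of the floored values. Where the lower group has an array at the floor, the fold is written as "at least" if it also lies below the ratio of the mean intensities. For Prkcb it does not, so its log2 change is given in place of a fold. Detection calls were not used here. Probe sets were tested when their mean log2 value over the 4 arrays lay above the 40th percentile, which left 7453 probe sets of 5701 genes. Dim probe sets that were on in 1 group only can fall under this filter.

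Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided) as transgenic minus control, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The fit had 2 residual degrees of freedom per probe set, to which the shared variance estimate added 7.51, and the median SE of a log2 change was 0.188. The number of arrays limits the precision. SEs beside log2 changes come from that fit, as do adjusted p-values of genes unless another setting is named. Errors beside intensities are SDs over 2 pools.

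Gene lists were tested with camera in limma at its preset inter-gene correlation of 0.01, and with an estimated correlation beside it. Each list was read from 1 probe set per gene (the brightest tested one) and needed at least 5 tested members. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit, at which few lists can pass after adjustment. Failing to pass in that setting therefore does not argue against a list. P-values were adjusted over the lists tested. List values with an estimated correlation come from all 4 arrays, also where they stand beside a value with 1 array left out, so the 2 are not like for like. The counts of members that rose or fell come from a limma fit with 1 probe set per gene, in which 556 genes passed, 290 higher and 266 lower. The 31 lists cover cholinergic genes, immediate early genes, glutamate receptors, GABA signalling, monoamine receptors, synaptic vesicle, postsynaptic density, potassium channels, sodium and calcium channels, water and ion transport, splicing factors, glucocorticoid response, heat shock and chaperones, interferon and antigen presentation, apoptosis, myelin, astrocyte, microglia, endothelial, choroid plexus, striatum, olfactory bulb and migrating neuroblasts, interneuron, cortical projection neuron, blood, sex genes, circadian clock, oxidative phosphorylation, ribosomal proteins, proteasome and histones. Some genes stand in more than 1 list.

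Named genes followed a rule: every tested member of the cholinergic list, the 12 largest rises and 12 largest falls among probe sets that passed with groups that did not overlap (1 probe set per gene), Xist, and the 3 members of smallest p in each list that passed. The same 3 were taken from the lists cholinergic, immediate early genes, glutamate receptors, GABA signalling, myelin, astrocyte, splicing factors, water and ion transport, heat shock and striatum whether or not they passed. Other genes, among them further list members, other probe sets of named genes, Chrm4, the haemoglobins and the Y-linked genes, are named after their values were seen. Ranks among the largest rises include lower bounds. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

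The alternatives were quantile normalization, median scaling and cyclic loess, floors at the 10th and 40th percentiles, no filter and a filter at the 60th percentile, eBayes without the trend and with a robust prior, the replicate number as a block, each array left out in turn, and for lists the mean of a gene's probe sets and an estimated correlation. After seeing the data, these were added: counting 1 probe set per gene, leaving out genes with a probe set changed over 4-fold, and reading each gene in a list from its probe set of lowest absolute change. Probe sets of the same gene were compared where their source accessions differed. The fit was tested on simulated data for the 7453 probe sets, in which 63% of changes of 1 log2 unit and 96% of changes of 2 log2 units were recovered, with 1 false call, and data without any change gave 0 calls. Each simulated value took its residual at random from a probe set of similar level, separately for each array. The simulation thus held no batch or other effect shared by an array or group, and its false calls do not bear on those. It also evened out differences in variance between probe sets of similar level. Its recovery and false calls may therefore look better than those of the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.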

Results

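Gene expression was measured in the prefrontal cortex of female mice that overexpress human synaptic acetylcholinesterase (AChE), the enzyme that breaks down acetylcholine, and in control female mice of the FVB/N strain. Each array was hybridised with RNA pooled from 4 mice. There were 2 control pools and 2 transgenic pools, so the number of arrays limits the precision of every value. Each array gave an intensity for 12422 probe sets after control probe sets were set aside, and 10833 of these carried a single gene name. Median intensity was 87.4 and 86.6 in the control pools and 87.45 and 88.2 in the transgenic pools. Pools of the same group resembled each other more than pools of different groups did. The log2 intensities correlated across probe sets at r = 0.976 between the control pools and 0.972 between the transgenic pools, against 0.912 to 0.918 between groups. The mean absolute log2 difference between arrays was 0.243 and 0.268 within groups and 0.399 to 0.43 between them. Probe sets are not independent replicates, so these values describe the arrays only.

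The signal of the mouse gene for acetylcholinesterase was lower in the transgenic pools. Its probe set (Ache, 104650_at) read 599.5 and 621.9 in the control pools and 365.3 and 355.6 in the transgenic pools, a 1.69-fold fall (log2 change -0.76 ± 0.14 SE, adjusted p = 0.00768). The probe set was designed on the mouse transcript. Whether it also detects the human transgene is not given in the sources used here, so it does not check the transgene. Among the receptors for acetylcholine, the muscarinic receptor Chrm1 fell 2.57-fold, from 408 ± 82.5 to 157 ± 2.55 (SD, n = 2 pools per group; log2 change -1.36 ± 0.19 SE, adjusted p = 0.00128). The nicotinic receptor subunit Chrna7 had a log2 change of -0.44 ± 0.21 (adjusted p = 0.231). Colq, which anchors AChE at the neuromuscular junction, had -0.41 ± 0.24 (adjusted p = 0.351). Ly6h, a modulator of nicotinic receptors, had 0.43 ± 0.14 (adjusted p = 0.0798), and the choline transporter Slc44a1 had 0.00 ± 0.19 (adjusted p = 0.993). Of the 6 tested members of the cholinergic list, 0 rose and 2 fell, and adjusted over the list alone 1 rose and 2 fell. The list as a whole had a median log2 change of -0.42 and did not pass (camera adjusted p = 0.224, 0.838 with an estimated correlation and 0.0247 without the intensity filter). A second muscarinic receptor, Chrm4, lay under the intensity filter and was not tested. Its probe set read 92.3 and 93.4 in the control pools and 12.6 and 23.3 in the transgenic pools, and it is named after its values were seen. Without transgenic replicate 1 the adjusted p of Ache was 0.0608, and without transgenic replicate 2 it was 0.0723 for Ache and 0.0518 for Chrm1. Without control replicate 2 it was 0.0328 for Ly6h.

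All pools are labelled female, and the Y-linked genes Kdm5d, Eif2s3y and Uty read 28 or less on every array. Xist, the RNA that coats the inactive X chromosome of female cells, read 29.3 and 21.1 in the control pools and 178.5 and 228 in the transgenic pools (log2 change 3.02 ± 0.31 SE, adjusted p = 0.000165). The Xist signal of the control pools thus lay close to the intensity floor of 19.675, so it does not show the labelled sex of those pools. With an 8.11-fold rise, Xist is also among the probe sets over 4-fold higher in the transgenic pools.

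The main comparison asked which genes differ between transgenic and control prefrontal cortex. Mef2c, a transcription factor of neurons, rose most, by 5.60 ± 0.27 on the log2 scale at probe set 104592_i_at (at least 48.4-fold, with 1 of 2 control arrays at the floor). It also rose by 4.74 at 104590_at and 3.32 at 104591_g_at, and 97357_at did not pass. Cmip rose at least 44.2-fold at 103748_at, and the transcription factor Klf13 rose at least 41.3-fold at 160617_at, each with both control arrays at the floor. The nuclear factors Nfix and Nfib rose 33.5-fold and 28.7-fold, and the protein kinase C gene Prkcb rose by 4.84 ± 0.33 on the log2 scale, with 1 of 2 control arrays at the floor. Mapt, which encodes the microtubule protein tau, rose 27.4-fold, from 124 ± 11.4 to 3403 ± 18.7 (SD, n = 2 pools per group). Cd47, a surface protein that restrains phagocytosis, rose 27.0-fold, and Gpd2, a mitochondrial glycerol phosphate dehydrogenase, rose 26.5-fold. The potassium channel Kcna1 and the RNA-binding protein Elavl3 rose at least 25.8-fold and at least 24.8-fold over control arrays at the floor, and the calcium-activated potassium channel Kcnma1 rose 20.8-fold. The adjusted p of these 12 probe sets was at most 1.11e-05, the value of Prkcb.

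Falls were smaller. The beta-actin gene Actb fell most among single named genes, 6.07-fold at 95705_s_at (log2 change -2.60 ± 0.14, adjusted p = 2.69e-06). In contrast, the 3 control probe sets for beta-actin on the array, which were not tested, were higher in both transgenic pools, with log2 changes of 1.17, 1.28 and 1.004. The sialyltransferase gene St6galnac6 fell 5.50-fold, though its transgenic pools differed widely (28.5 and 143.5). The lipid kinase Pip5k1c fell 5.18-fold, the growth factor Fgf1 4.80-fold, Erdr1 4.62-fold and the lysosomal protein precursor Psap 4.59-fold. Capzb, which caps actin filaments, fell 4.54-fold, and the imprinted noncoding RNA Meg3 fell 4.49-fold at 160172_at. Pgs1 fell at least 4.28-fold, with 1 of 2 transgenic arrays at the floor, and Nsmf, Usf1 and Krt12 fell 3.84-fold, 3.68-fold and 3.57-fold. The adjusted p of Pgs1, 0.0109, was 0.103 and 0.0648 without transgenic replicate 1 or 2, 0.0559 without control replicate 1 and 0.0838 with a floor at the 40th percentile. That of St6galnac6, 0.0244, was 0.128 without the intensity trend and 0.159 with a robust prior.

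In all, 747 of 7453 tested probe sets passed, 407 higher and 340 lower in the transgenic pools, and 1811 had an unadjusted p under 0.05. The balance depended on the setting: with a filter at the 60th percentile 300 were higher and 347 lower, and without the intensity trend 272 were higher and 123 lower. Large changes were mostly rises. A log2 change over 2 was reached by 118 rises and 15 falls, and one over 3 by 60 rises and 2 falls. Without the filter on dim probe sets 48 passed, and of the 55 named probe sets that passed 8 still did: those of Klf13, Nfix, Mapt, Cd47, Gpd2, Elavl3, Gria1 and Gabrb1. Without the intensity trend 395 passed in all, and leaving out transgenic replicate 1 or 2 left 303 and 313.

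**Figure D1:**
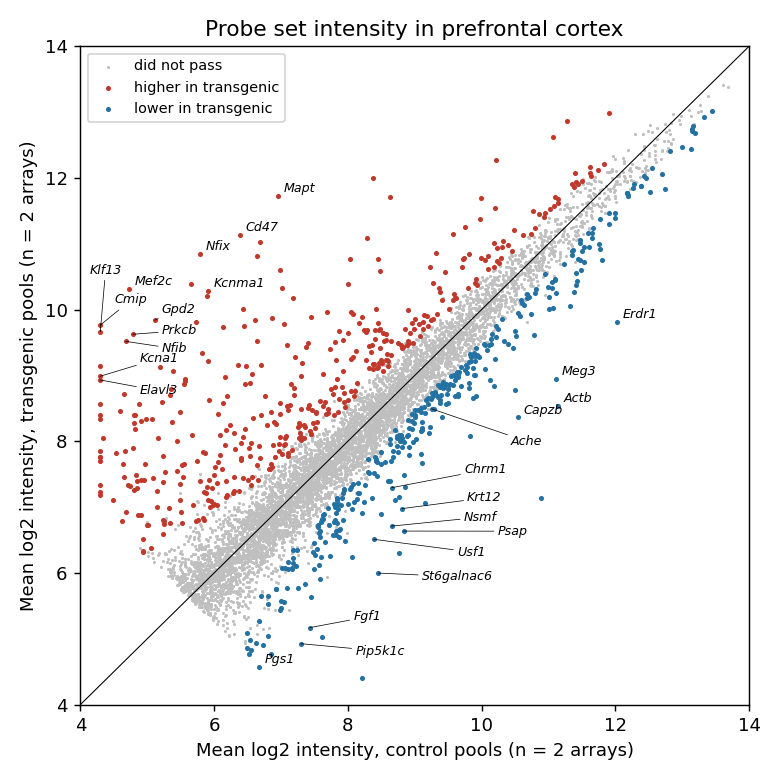
Mean log2 intensity of each tested probe set in the control pools (horizontal axis) and the transgenic pools (vertical axis), n = 2 arrays per group, with the line of equal values. Red and blue points are the 407 probe sets that passed as higher and the 340 that passed as lower in the transgenic pools, grey points did not pass, and the column of red points at the left edge has both control arrays at the floor.

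Several of the genes with the largest rises were also read by a probe set made from another sequence, and these often did not move. A second probe set of Nfix (100307_at) had a log2 change of 0.17 ± 0.21, and that of Cd47 (95020_at) -0.12 ± 0.14, and neither passed. Mef2c rose at 3 of its 4 probe sets, and the fourth (97357_at) had 0.14 ± 0.21 and did not pass. For Klf13 the second probe set (103369_at) fell by 1.22, and for Prkcb (99510_at) it fell by 0.40. Cmip rose by 0.47 at its other probe set (103584_at, adjusted p = 0.0192). Meg3, which fell at 160172_at, rose by 3.32 at 160173_at. Of 97 genes with a probe set over 2 log2 units higher, 39 had a tested probe set of another accession than the most risen one. Over these genes the other probe sets had a median log2 change of 0.15 (quartiles -0.12 and 0.66). Mef2c is not among the 39, because its most risen probe set has no accession listed. In 10 genes another probe set rose too, in 4 another fell, and in 26 the median of the others lay within 0.5 of 0. A gene can stand in more than 1 of these counts, as Cmip and Prkcb do. Some genes rose at every accession: Mapt rose by 4.78, 4.34 and 2.32 at 3 probe sets, Gria2 by 3.23, 2.44 and 2.06, Nfib by 4.84 at both (with both control arrays at the floor for 1 of them), and Aqp4 by 3.69 and 2.10. Among the falls, Actb fell at both of its tested probe sets, by 2.60 and 1.18, while the 3 control probe sets for beta-actin moved the other way. The probe set that fell by 1.18 (101578_f_at) is listed under the same source sequence as these control probe sets. Probe sequences were not given in the sources used here, so whether they share probes or targets cannot be told. Other probe sets of Capzb, Nsmf and Usf1 had log2 changes of -0.29, -0.21 and -0.17, those of Psap -0.41 and -0.07 and that of Erdr1 0.66, and none of these passed.

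**Figure D2:**
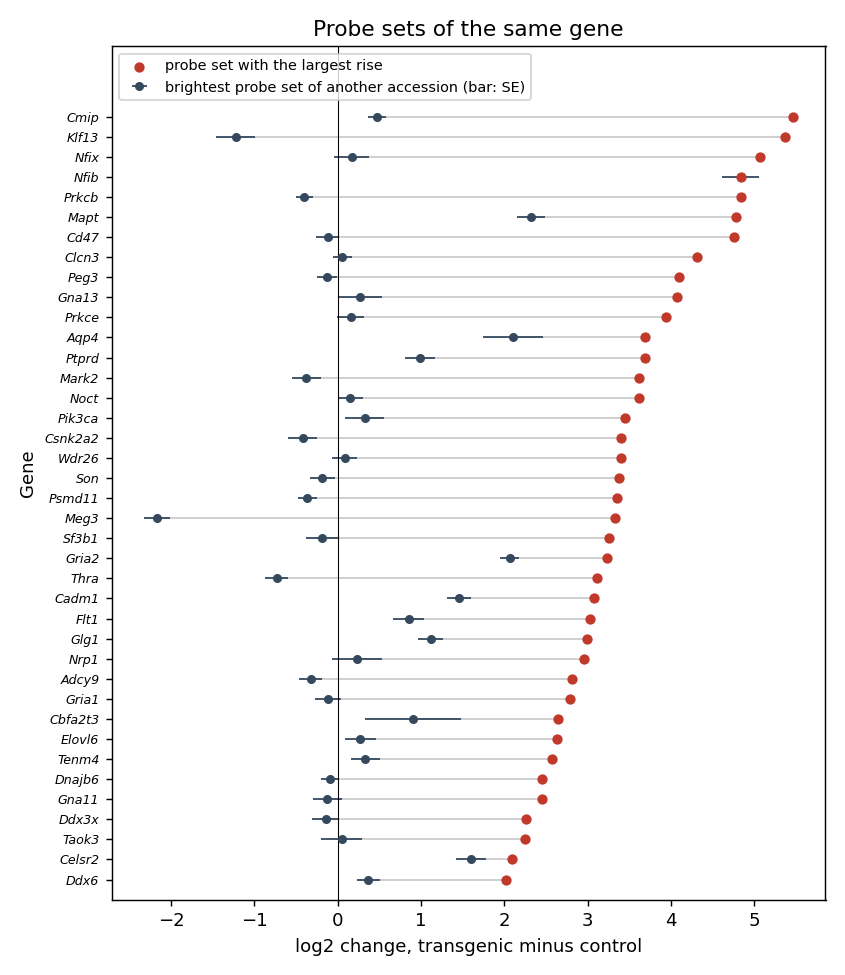
Log2 change (transgenic minus control, n = 2 arrays per group) for 39 genes with a probe set over 2 log2 units higher: red, the probe set with the largest rise; dark, the brightest tested probe set of another accession, with its SE. Most dark points lie near 0, while those of Nfib, Mapt, Aqp4 and Gria2 lie above 2.

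Among receptors of excitatory transmission the calls were rises, and GABA signalling genes moved both ways. The AMPA receptor subunits Gria1 and Gria2, which carry fast excitatory currents, rose by 2.79 ± 0.13 and 2.06 ± 0.11 on the log2 scale (adjusted p = 8.90e-07 and 2.69e-06). A second Gria1 probe set (92944_at) had -0.12 ± 0.15, whereas all 3 Gria2 probe sets rose. Among 9 glutamate receptor genes 2 rose and 0 fell, and Grid1 had -0.46 ± 0.16 (adjusted p = 0.116). The GABA type A receptor subunit Gabrb1 rose 12.2-fold, from 127 ± 0.636 to 1555 ± 10.04 (SD, n = 2 pools per group; adjusted p = 3.75e-07). Another subunit, Gabra3, fell 2.94-fold (adjusted p = 0.0192), and Gabrd had -0.57 ± 0.16 (adjusted p = 0.0566, 0.0496 with median scaling and 0.0418 with a filter at the 60th percentile). Of 9 GABA signalling genes 1 rose and 1 fell. Adjusted over the list alone the counts were 2 and 0 for glutamate receptors and 2 and 2 for GABA signalling. Neither list passed (camera adjusted p = 0.423 and 0.703), but glutamate receptors did without control replicate 1 (0.0476) or control replicate 2 (0.0204), against 0.854 with an estimated correlation. Gabra3 had an adjusted p of 0.0872 without transgenic replicate 1 and 0.0507 without the intensity trend.

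Genes of the release machinery and of ion channels moved both ways. Of 19 synaptic vesicle genes 4 rose (Syt4 by 2.35, Cplx2 by 1.37, Syt11 by 1.21 and Napb by 1.12 on the log2 scale) and 4 fell (Cplx1 by 1.27, Vamp1 by 0.95, Napa by 0.85 and Snap25 by 0.37), with a list median of -0.37. A second Napb probe set (92952_f_at) had -0.02 ± 0.27 and did not pass. The complexins Cplx1 and Cplx2, which regulate vesicle fusion, thus moved in opposite directions. Of 11 postsynaptic density genes Homer2 rose by 0.68, and Camk2a, the calcium-dependent kinase of excitatory synapses, fell by 1.54. Baiap2 had -0.54 at the probe set used in the list but rose by 1.14 at 103098_at. Of 20 potassium channel genes Kcna1, Kcnma1 and Kcnd2 rose and Kcnj4, Kcnk1 and Kcnj11 fell, and a second Kcnd2 probe set (98364_at) had 0.24 ± 0.50 and did not pass. Of 10 sodium and calcium channel genes the calcium channel accessory gene Cacng2 rose by 2.67, the sodium channel Scn8a by 2.34, Cacna2d1 by 1.48 and Cacna1c by 0.67, and Cacna1a fell by 1.18. Adjusted over the list alone, 4 rose and 8 fell among synaptic vesicle genes, 1 and 1 among postsynaptic genes, 5 and 3 among potassium channels and 4 and 2 among sodium and calcium channels. None of the 4 lists passed (camera adjusted p = 0.695, 0.644, 0.825 and 0.423). Potassium channels passed without control replicate 1 (0.0476), and sodium and calcium channels without control replicate 2 (0.0308), against 0.854 for both with an estimated correlation. Of 9 monoamine receptor genes 0 passed, over all probe sets or adjusted over the list alone (camera adjusted p = 0.825).

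Astrocyte genes split. The water channel Aqp4, which sits on astrocyte endfeet, rose 12.9-fold, from 42.1 ± 7.64 to 554 ± 184 (SD, n = 2 pools per group; adjusted p = 1.49e-05). The fatty acid binding protein Fabp7 rose 2.91-fold (adjusted p = 3.27e-05) and the metallothionein Mt1 rose 1.52-fold (adjusted p = 0.0104). The brain metallothionein Mt3 fell 1.87-fold (adjusted p = 0.00262), S100b fell by 0.67, Clu by 0.53 and Apoe by 0.40 on the log2 scale. A second Clu probe set (161294_f_at) had -0.16 ± 0.13 and did not pass. In total 3 of 19 tested astrocyte genes rose and 4 fell, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.947). Of 20 water and ion transport genes 3 rose and 2 fell, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.899). The bicarbonate transporter Slc4a4 rose 3.63-fold (adjusted p = 0.00282) and the sodium-calcium exchanger Slc8a1 2.14-fold (adjusted p = 0.00502), while Fxyd7 fell by 0.76 and the neuronal chloride exporter Slc12a5 by 1.17. The chloride transporter gene Clcn3 had 0.06 at the probe set used in the list but rose by 4.31 at 94464_at and 3.52 at 94465_g_at. Without transgenic replicate 2 the adjusted p of Slc8a1 was 0.101 and that of Slc4a4 0.0542, and without transgenic replicate 1 it was 0.0553 for Slc4a4 and 0.0815 for Mt1. Without the intensity trend it was 0.0620 for Mt3 and 0.109 for Mt1.

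The list of myelin genes did not pass (camera adjusted p = 0.835). Of 12 tested members, each read from 1 probe set, 0 rose and 1 fell, also when adjusted over the list alone. Mobp, a myelin protein gene, had 0.06 at the probe set used in the list but fell by 1.02 at 99047_at (adjusted p = 0.00955), with -0.85 and -0.65 at 2 others that did not pass. Qdpr, an enzyme of biopterin recycling that oligodendrocytes express, fell 1.55-fold (adjusted p = 0.00894), but its adjusted p was 0.0815 without transgenic replicate 1 and 0.0894 without the intensity trend. Mag, a myelin adhesion protein, had a log2 change of -0.59 ± 0.24 (adjusted p = 0.169, and 0.00238 without control replicate 1), and Gsn had 0.28 ± 0.15 (adjusted p = 0.300). Microglia and macrophage genes gave 0 rises and 1 fall of 15 (camera adjusted p = 0.328), the fall being Tyrobp, a signalling adaptor of microglia (log2 change -0.95 ± 0.19, adjusted p = 0.0127). Adjusted over the list alone the fall count was 2. Of 15 endothelial and mural genes the vascular growth factor receptor Flt1 rose and 0 fell, also over the list alone (camera adjusted p = 0.825). Of 12 choroid plexus and meningeal genes 0 passed, over all genes or over the list alone (camera adjusted p = 0.825), though Ptgds fell by 0.64 at a probe set not used in the list (92546_r_at). All 9 tested interferon and antigen presentation genes had log2 changes below 0 (median -0.31), and 0 of them passed, over all probe sets or over the list alone (camera adjusted p = 0.141).

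Of 29 lists tested, 4 passed with camera at its preset correlation, all towards higher signal in the transgenic pools: ribosomal proteins, immediate early genes, olfactory bulb and migrating neuroblasts, and glucocorticoid response. With an estimated correlation 0 of 29 passed, each of these 4 having an adjusted p of 0.768. The estimates were -0.025 for ribosomal proteins, -0.038 for immediate early genes, -0.066 for glucocorticoid response and 0.052 for the olfactory list. Where the estimate lay below the preset 0.01, a higher correlation does not account for the larger p. In that setting camera has only the 2 residual degrees of freedom of the fit. Its smallest unadjusted camera p was 0.0435, for ribosomal proteins, so 0 of 29 passing does not argue against the 4 lists. Each gene was read from 1 probe set, and 9 list members that were not called there were called at another of their probe sets. Most ribosomal protein genes were slightly higher. Their median log2 change was 0.31 over 25 tested members, of which 4 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000915, and 0.768 with an estimated correlation). Rps19 rose 2.05-fold (adjusted p = 0.00394) and Rpl10a 1.43-fold (adjusted p = 0.0237), Rps28 (98085_f_at) and Rps3a1 rose by 0.44 and 0.39 on the log2 scale, and Rps13 fell 3.53-fold (adjusted p = 0.00137). Without control replicate 1 the list had an adjusted p of 0.0764, and without control replicate 2 it had 0.0745. Without transgenic replicate 1 or 2 the adjusted p of Rps19 was 0.0865 and 0.113 and that of Rpl10a 0.0887 and 0.138, and for Rpl10a it was 0.0959 without control replicate 2. Without the intensity trend it was 0.0571 for Rps19 and 0.130 for Rpl10a.

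Immediate early genes, which neurons switch on when active, had a median log2 change of 0.32 over 23 members. Of these 3 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00749, 0.768 with an estimated correlation and 0.0565 without control replicate 2). The neurotrophin Bdnf rose 2.63-fold, from 313 ± 5.59 to 828 ± 79.4 (SD, n = 2 pools per group; adjusted p = 0.000179). The orphan nuclear receptors Nr4a2 and Nr4a1 rose 2.61-fold (adjusted p = 0.00749) and 1.48-fold (adjusted p = 0.0182). The classical members Fos and Egr1 had log2 changes of 0.33 and 0.38 and did not pass. Without transgenic replicate 1 or 2 the adjusted p of Nr4a2 was 0.0512 and 0.101 and that of Nr4a1 0.0800 and 0.115, and for Nr4a1 it was 0.0556 without control replicate 1 and 0.101 without the intensity trend.

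Genes that respond to glucocorticoid hormone had a median log2 change of 0.28 over 14 members, with 3 rises and 1 fall, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0438, and 0.768 with an estimated correlation). Klf9, a transcription factor, rose 2.68-fold at 93528_s_at (adjusted p = 0.000116) but fell by 0.99 at 93527_at. Nfkbia, the inhibitor of NF-kappaB, rose 2.01-fold (adjusted p = 0.00409), with 0.05 ± 0.19 at a second probe set, and Mt1, which also responds to metals, rose 1.52-fold. The transcription factor Zbtb16 fell by 0.56. The hormone-induced genes Fkbp5 and Sgk1 had log2 changes of 0.09 and 0.01 and did not pass. The list had an adjusted p of 0.176 without control replicate 2, 0.0813 without transgenic replicate 2, 0.0858 with a floor at the 40th percentile, 0.147 without the intensity filter, 0.294 with each gene's probe sets averaged and 0.826 with each gene's probe set of lowest absolute change. Without transgenic replicate 1 or 2 the adjusted p of Nfkbia was 0.0540 and 0.0735. Heat shock and chaperone genes did not pass (camera adjusted p = 0.0785, and 0.815 with an estimated correlation). Of 23 members 3 rose, also over the list alone, and 0 fell: Pdia3 by 0.79, the cytosolic chaperone Hspa8 by 0.48 and the endoplasmic reticulum chaperone Hsp90b1 by 0.46 (adjusted p = 0.0454, 0.0437 and 0.0392). The list passed with transgenic replicate 1 left out (adjusted p = 0.0320), and under 5 other settings, with adjusted p from 0.0247 to 0.0449, against 0.815 with an estimated correlation. All 3 genes had adjusted p above 0.05 without transgenic replicate 2 (0.260, 0.236 and 0.142) and without the intensity trend (0.154, 0.193 and 0.164). Hspa8 had 0.0793 without transgenic replicate 1 and 0.174 without control replicate 2, and Hsp90b1 had 0.143, 0.0537 and 0.185 without transgenic replicate 1, control replicate 1 and control replicate 2. Pdia3 and Hspa8 also lost their calls with quantile normalization (0.0656 and 0.0619) and a floor at the 40th percentile (0.0593 and 0.0534), and Pdia3 with a robust prior (0.0515).

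Genes of the olfactory bulb and of migrating neuroblasts had a median log2 change of 0.59 over 11 members, of which 4 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.00993, 0.768 with an estimated correlation, 0.0565 without control replicate 2 and 0.0603 with each gene's probe set of lowest absolute change). The homeobox gene Pbx3 rose 3.04-fold at 93615_at (adjusted p = 0.000562), with 0.44 at 93616_g_at, which did not pass, and 0.05 ± 0.20 at a probe set of another accession. Sox11, a factor of immature neurons, rose 2.69-fold (adjusted p = 0.00497), Eomes 2.99-fold (adjusted p = 0.0396) and Th, the rate-limiting enzyme of dopamine synthesis, by 0.65 on the log2 scale. Omp, the marker of olfactory sensory neurons, had -0.03, and Dcx, a marker of migrating neurons, had 0.27. Without transgenic replicate 1 the adjusted p was 0.0530 for Pbx3, 0.0873 for Sox11 and 0.205 for Eomes. For Eomes it was also 0.205 without transgenic replicate 2, 0.0959 without control replicate 2, 0.0733 without the intensity trend and 0.0561 with a floor at the 40th percentile. In the striatum list Meis2, a homeobox gene, rose 2.13-fold (adjusted p = 0.00800, and 0.102 and 0.0506 without transgenic replicate 1 or 2) as the single call of 10 members, over all probe sets and over the list alone. The phosphodiesterase Pde1b had -0.50 ± 0.18 (adjusted p = 0.122, and 0.00951 without control replicate 1) and Ido1, with 1 of 2 transgenic arrays at the floor, -0.90 ± 0.60 (adjusted p = 0.407). The striatum list did not pass (camera adjusted p = 0.899).

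Markers of cortical neuron classes also moved both ways. Among 18 interneuron genes the calcium-binding protein Calb2 rose by 0.75 on the log2 scale, and the neuropeptides Npy and Sst fell by 0.71 and 0.56. Adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.825). Among 14 genes of cortical projection neurons Cdh13 rose by 2.69, the transcription factor Neurod2 rose by 2.07 and Camk2a fell by 1.54, with the same counts over the list alone (camera adjusted p = 0.835). In that list Mef2c was represented by 97357_at, with 0.14, and its 3 risen probe sets were not used. Haemoglobin signal was higher in the transgenic pools: Hba-a1 read 2678 and 2325 in the control pools and 8257 and 6741 in the transgenic pools (log2 change 1.58 ± 0.13, adjusted p = 3.27e-05). Alas2, the haem synthesis enzyme of red cell precursors, rose by 1.30 ± 0.23 (adjusted p = 0.00645). The blood list had 4 tested members, too few for its test, of which 2 rose and 0 fell, and the list of sex genes had 3, of which Xist rose.

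Within the splicing list, the neuronal RNA-binding proteins of the Elav family rose. Elavl3, Elavl4 and Elavl2, which bind AU-rich messages and regulate neuronal splicing, were higher by at least 4.63, by 3.47 ± 0.24 and by 1.70 ± 0.21 on the log2 scale (adjusted p = 1.53e-06, 1.44e-05 and 0.000734), with both control arrays at the floor for Elavl3. Each of the 3 was read by a single tested probe set. Elavl1, the widely expressed member, had 0.24 ± 0.19 (adjusted p = 0.505). The remaining splicing factors were mixed: Hnrnpc and Srsf3 rose by 0.91 and 0.85, and Hnrnpa1 and the splicing kinase Clk4 fell by 1.27 and 0.86. Second probe sets of Srsf3 and Clk4 had 0.45 and -0.73 and did not pass, and Sf3b1, with -0.19 at the probe set used in the list, rose by 3.26 at 97808_at. Of 35 splicing genes 5 rose and 2 fell, and 6 and 6 adjusted over the list alone, with a list median of -0.16 (camera adjusted p = 0.825). The mitochondrial and proteasome lists did not pass. Of 62 oxidative phosphorylation genes 5 rose and 2 fell, also over the list alone, with a median of 0.05 (camera adjusted p = 0.149, 0.0458 with cyclic loess and 0.768 with an estimated correlation). The largest change among them was the rise of Ndufb3 by 0.95. Of 38 proteasome genes Psmc5 rose by 0.57 and Psmd5 fell by 1.08, also over the list alone (camera adjusted p = 0.825). Psmd11 had -0.36 at the probe set used in the list but rose by 3.36 at 160305_at. Of 17 apoptosis genes cytochrome c (Cycs) was the single rise with 1 probe set per gene, and 0 passed over the list alone (camera adjusted p = 0.825), while Dffa fell by 0.83 at a probe set not used in the list (99485_at). Of 5 histone genes 0 passed, and 2 rose over the list alone (camera adjusted p = 0.423, 0.0476 without control replicate 1 and 0.854 with an estimated correlation). Of 16 circadian clock genes 1 rose and 4 fell, and 2 and 5 over the list alone (camera adjusted p = 0.394). The median and the test differed in sign for glutamate receptors, potassium channels, sodium and calcium channels, splicing factors, apoptosis, cortical projection neuron, striatum, choroid plexus, interneuron and myelin genes. The mean and the test differed for striatum, choroid plexus, astrocyte and water transport genes.

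**Figure D3:**
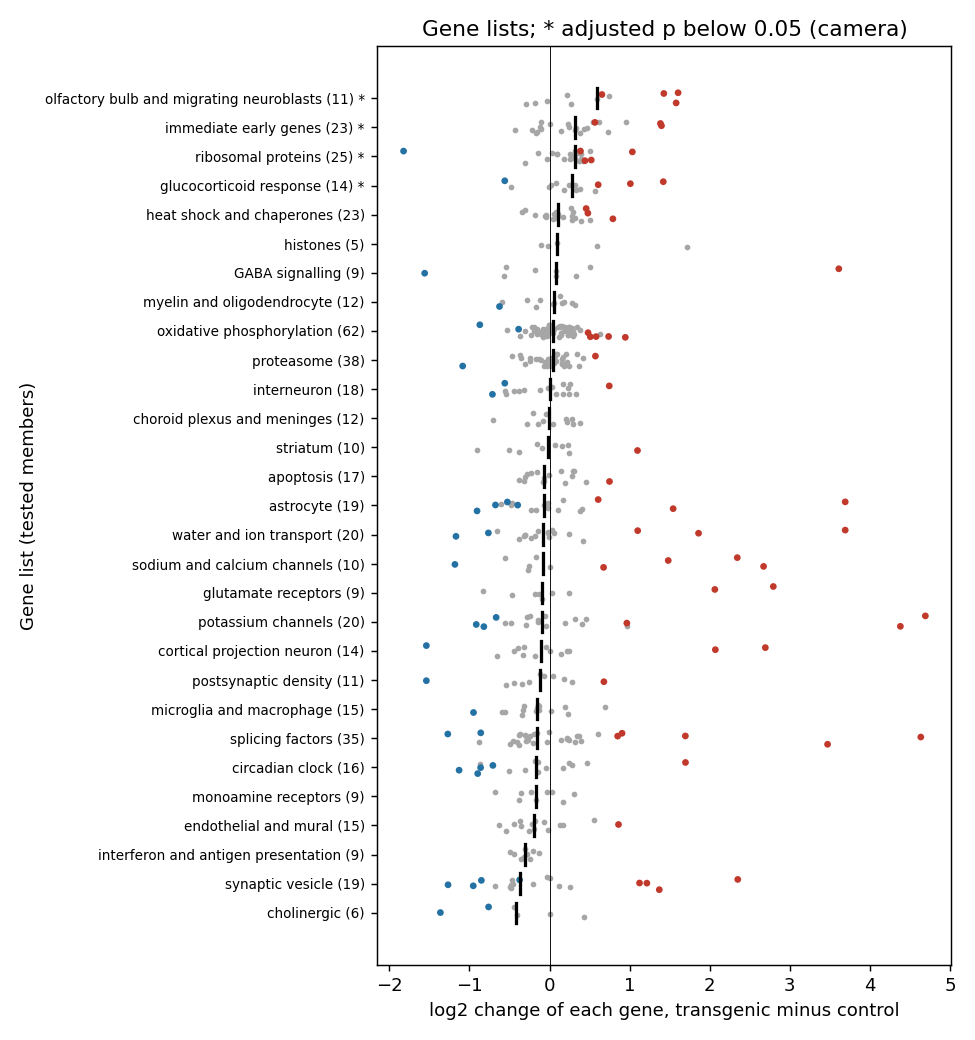
Log2 change (transgenic minus control, n = 2 arrays per group) of every tested gene in 29 gene lists, with 1 probe set per gene. Red and blue points passed as higher and lower, grey points did not pass, the black bar is the list median and an asterisk marks the 4 lists that passed camera, whose medians lie between 0.28 and 0.59.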

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

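All tests in this part were chosen after the results they bear on were seen.

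The array carries control probe sets for mouse genes that were left out of the test, and those for beta-actin differed between the groups. They were higher in both transgenic pools at the 3′ part (log2 change 1.17, from 3690 ± 78.4 to 8316 ± 270), the middle (1.28) and the 5′ part (1.004) of the transcript (SD, n = 2 pools per group), by 0.99 to 1.38 under other scalings. The Actb probe sets in the main comparison fell by 2.60 and 1.18, the latter being listed under the same source sequence as the control probe sets. The 3 control probe sets of Gapdh had log2 changes of -0.26, -0.51 and -0.48, and -0.02 to -0.26 after quantile normalization. The 3′ control probe set of the transferrin receptor was lower in both transgenic pools (log2 change -0.92, and -0.86 to -0.93 under other scalings), as was a middle probe set of pyruvate carboxylase (-1.19, and -1.14 to -1.22).

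The first pattern is the rise of probe sets over 4-fold in the transgenic pools, such as those of Nfix and Cd47. A change of the whole transcript could be examined in 39 of 97 genes, chosen by the rise alone. It is argued against for these 39 as a set, not for each gene. These had a tested probe set of another accession than the most risen one, with a median log2 change of 0.153 (quartiles -0.12 and 0.66). A whole-transcript change stays open for the 10 of them in which another accession rose too (Aqp4, Cadm1, Celsr2, Cmip, Flt1, Glg1, Gria2, Mapt, Nfib and Ptprd). In Cmip, Flt1 and Ptprd that rise was 0.47, 0.85 and 0.99, against 5.47, 3.03 and 3.69 at the most risen probe set. In the rest of the 10 it was 1.12 to 4.84. More degraded RNA in the control pools would give those pools the higher 3′ to 5′ ratio. The mean log2 ratio over actin, Gapdh and pyruvate carboxylase control probe sets ran the opposite way. It was 0.946 and 0.911 in the control pools and 1.23 and 1.03 in the transgenic pools. Gapdh and pyruvate carboxylase each had this order, and for actin the groups overlapped. The difference of -0.204 was no more than the 0.205 between the 2 transgenic pools, so degradation cannot be told apart. A labelling or hybridisation batch that follows the groups cannot be told apart from the transgene, as 0 label lines name a batch, scan, lot or date. An effect of the transgene on which ends or splice forms of a transcript are made may also give this pattern and stays open as an untested hypothesis.

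The second pattern is the higher haemoglobin signal. More blood in the transgenic tissue is consistent with the near-equal rises of Hba-a1 (1.58) and Hbb-b2 (1.70), whose log2 changes differed by 0.124 against a summed SE of 0.240, and Alas2 rose by 1.30. Bpgm, which brain also expresses, had 0.08. A difference in red cell transcripts caused by the transgene would raise these genes too and stays open, untested.

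The third pattern is the shift of the olfactory bulb and neuroblast list, of which Th, Tbr1, Dlx1, Dlx2 and others are also made elsewhere in the forebrain. If single probe sets produced it, the list might lose its shift when each gene is read from its probe set of lowest change. Its median then fell from 0.59 to 0.271, and its camera adjusted p was 0.0416, against 0.0603 with each gene's probe set of lowest absolute change and 0.768 with an estimated correlation, while 1 of its 11 members has more than 1 tested probe set, so this cannot decide. More olfactory bulb tissue in the transgenic pools cannot be told apart either: 3 of 11 members lay below 0, but 0 of them by more than 2 SE, with log2 changes from -0.30 to 1.60. The brightest member, Tbr1, which also stands in the cortical projection neuron list, read 1608 in the control and 1416 in the transgenic pools, Dlx1 read 326 and 482, and a biological effect of the transgene stays open, untested.

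The comparison itself rests on 2 arrays against 2. The 4 arrays can be split in 3 ways, and 1 of the 3, the real one, gave 747 probe sets past the threshold, the highest of the other splits giving 0. There are too few splits for a share under 0.05.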

How the results depend on the processing

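The counts with 1 probe set per gene, without genes with a probe set over 4-fold changed, and with the probe set of lowest absolute change were chosen after seeing the data. Where 1 array was left out, the remaining array of its group was assumed to vary like those of the other group. The number of probe sets past the threshold was 747 (407 higher, 340 lower), and 647 to 778 with other normalizations, floors, the robust prior or the 60th percentile filter, of which 566 to 738 were among the 747. It was 48 with no filter (34 higher, 14 lower), where 2155 probe sets at the floor on all 4 arrays have no variance and the prior degrees of freedom fell from 7.51 to 0.748. It was 395 without the intensity trend (123 lower; the cause was not tested). Leaving out 1 array gave 303 to 749 (180 to 435 higher, 102 to 314 lower). One probe set per gene gave 556 (290 higher, 266 lower). Leaving out genes with a probe set over 4-fold changed gave 582 (273 higher, 309 lower). That rule takes out mostly rises, as 118 rises and 15 falls lay over 2 log2 units, so its surplus of falls follows from the selection. Falls also outnumbered rises with the 60th percentile filter, with 647 (300 higher, 347 lower).

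Same-numbered pools did not deviate together (r = 0.0555 over probe sets, from 2 pairs). Probe sets are not replicates, so this does not exclude that pools were handled in pairs. With the replicate number as a block 892 passed, all 747 among them, and 4 lists. Of the named genes only Ly6h changed sides (adjusted p = 0.0288), and none changed direction.

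Of 55 named probe sets that passed, 33 kept their call in every setting other than no filter. No filter ended 47 calls, no trend 12, and leaving out transgenic replicate 1 or 2 ended 17 and 15. Signal near the floor limits what can be called: Chrm4 and other dim probe sets were not tested.

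The number of lists past the threshold was 4. It was 0 with an estimated correlation (adjusted p = 0.768 for each of the 4), a test on 2 residual degrees of freedom that few lists could pass. Reading each gene from its probe set of lowest absolute change gave 2 lists, the olfactory list having 0.0603 and the glucocorticoid list 0.826. Leaving out 1 array gave 2 to 6 lists. Without control replicate 2 none of the 4 passed (0.0745 for ribosomal proteins, 0.0565 for immediate early and for olfactory genes, 0.176 for glucocorticoid response), and the 2 that did were glutamate receptors (0.0204) and sodium and calcium channels (0.0308). Elsewhere 3 to 6 lists passed. No list or named gene past its threshold in either setting reversed its direction.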

Other observations

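The genes in this part were chosen after their values were seen. Of 16 tested genes of the circadian clock 4 fell and 1 rose, and the list as a whole did not pass (camera adjusted p = 0.394). Cry2, a repressor of the circadian clock, fell 2.19-fold, from 244 ± 7.64 to 112 ± 12.9 (SD, n = 2 pools per group; limma adjusted p = 0.00497). The output factors Dbp and Tef fell 1.86-fold and 1.82-fold (adjusted p = 0.00515 and 0.00340), and Nr1d2 fell 1.63-fold (adjusted p = 0.0305). Per2 had a log2 change of -0.87 ± 0.26 (adjusted p = 0.0677). The core activators Arntl and Clock had -0.15 ± 0.16 and 0.28 ± 0.20, and Per1, Per3 and Nr1d1 had 0.25, -0.18 and -0.15, none of which passed. Csnk1e, a kinase that acts on the PER proteins, rose 3.24-fold (adjusted p = 4.95e-05). Its relative Csnk1d had 0.47 at the probe set used in the list, which did not pass, and fell by 1.01 at 97263_s_at. The times at which the tissue was taken are not given in the labels.

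Among 622 genes with tested probe sets of 2 or more accessions, 150 had a call, and in 20 every accession was called the same way, 15 higher and 5 lower. Actb counts among the 5, although its control probe sets, which were not tested, moved the other way. Glo1, the enzyme that detoxifies methylglyoxal, rose by 1.34 ± 0.14 and 1.04 ± 0.12 at its 2 probe sets, from 351 to 888 and from 844 to 1738. Sox4, a factor of developing neurons related to Sox11, rose by 1.59 ± 0.22 and 0.99 ± 0.20, and Qk, an RNA-binding protein of glia, by 0.94 ± 0.15 and 0.72 ± 0.18. The adhesion genes Cadm1, Celsr2 and Ptprd also rose at every accession. Agrn, which organises synapses at the neuromuscular junction, fell by 0.54 ± 0.13 and 0.59 ± 0.14, and the receptor gene Gfra2 and the adaptor gene Ap2a2 fell at both of their accessions. In 5 genes (Klf13, Klf9, Meg3, Prkcb and Thra) accessions were called in opposite directions.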
